A study of Arabidopsis thaliana with 28 samples.

How the data were processed

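Transcript levels were measured on an Affymetrix Arabidopsis expression array in 28 samples of the entire aerial part of Arabidopsis thaliana seedlings of the accession Ws-2, with 4 samples in each of 7 groups. The groups were wild-type plants kept warm, wild-type plants given cold, warm plants overexpressing CBF1, CBF2 or CBF3 (called CBF1OX, CBF2OX and CBF3OX below), and plants overexpressing CBF2Δc, a truncated form of CBF2, kept warm or given cold. CBF1, CBF2 and CBF3 are transcription factors of the AP2/ERF family that bind the CRT/DRE promoter element and take part in cold acclimation. Plants grew for 11 d at 22 °C in constant light of about 100 µmol m-2 s-1, and the cold treatment lasted 24 h at 4 °C in constant light of about 35 µmol m-2 s-1. Cold plants therefore also differed from warm plants in light level and in age, and the design cannot separate these. Each of the 4 constructs was represented by 2 transgenic lines with 2 samples each, and replicates 1 and 2 came from the first line. The lines were G5 and G39 for CBF1OX, E2 and E24 for CBF2OX, A28 and A30 for CBF3OX, and DN89 and DN96 for CBF2Δc. The samples are called biological replicates in the labels, but how plants were pooled is not given in the sources used here, and p-values measure the spread between these samples.

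Per the labels' protocols, total RNA was extracted with a column kit, amplified and biotinylated. The deposited values are log2 expression values per probe set, made by the authors with GCRMA, per the submitters' processing notes, which also name limma. The versions, the probe definition and whether all arrays were processed together are not given in the sources used here. The log base was taken from the range of the values, 2.16 to 14.53. GCRMA subtracts background by sequence, so dim probe sets pile up near the lowest value, which held 11.6% of all values, and changes from such levels depend on that floor. Array medians ran from 4.98 to 5.08. The number of arrays, not a read depth, limits the precision here. Arrays of a group had a mean correlation with each other from 0.965 to 0.988.

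The table holds 22810 probe sets. The platform annotation used here gave 13513 of them 1 gene, 503 several genes and 8730 none, and 64 were Affymetrix controls, which were left out of the comparisons. A probe set with several genes or none was kept under its own identifier and is called unnamed below, which does not mean that it lacks a gene. CBF1, CBF2 and CBF3 had no named probe set, so the planned check of the labels by these genes could not be made by name and they could not be left out of counts. Some unnamed probe sets followed the constructs in warm plants, as given in the Results. Where a gene had several probe sets, the one with the highest mean was used. Features were tested if their log2 value was above 4 in at least 4 arrays, which left 14578 features, 7898 named genes and 6680 unnamed probe sets.

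Computations used R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. A single limma model (lmFit and eBayes) with a mean per group was fitted to all 28 samples, and each comparison was a contrast of these means. A feature was called at a Benjamini-Hochberg adjusted p below 0.05 over all 14578 features together with a change of at least 2-fold. In the text, rose, fell and called refer to this rule. Fold changes are given as log2 differences with the standard error of the fit.

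Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over 275 tests, 25 lists in 11 comparisons. Of 244 entries on lists written before the data were examined, 31 had a named probe set, and 5 of those lists had at least 3 members measured. The other 20 lists were built from gene symbols in the annotation before any comparison was computed. The rule for named genes was also set before the data were examined. It takes, for comparisons against wild type, the 10 highest and 10 lowest changes among called named genes whose samples did not overlap between groups, up to 4 called members of each list, and the 5 largest changes per direction for differences between overexpressors and for the interaction. A gene outside this rule is said to have been chosen after its values were seen.

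Genes called in the same direction in CBF1OX, CBF2OX and CBF3OX against warm wild type were taken as the common set. Their changes used no cold and no CBF2Δc sample, but the spread behind the calls was estimated from all 28 samples. Overlap of this set with the cold response and its median in CBF2Δc plants were planned before the data were examined. Scores per sample were added later. A score was the mean log2 level over such a set minus the mean of the 4 warm wild-type samples, compared by exact two-sided permutation tests over the 70 splits of 8 samples, with Benjamini-Hochberg adjustment over 25 tests. Because several comparisons share the warm wild-type samples, unchanged groups were simulated against those controls 100 times and the controls were split into 2 sets of 2. A model with a mean per line was added after the data were seen. Calls were also recomputed without a filter, with a stricter one, after centring arrays on their medians or quantile normalization, with array weights, with the line as a random block, with line means, with each line alone, with the replicate number as a block, with only the compared groups, with other thresholds and without each sample in turn. There, the common set was tested with camera's preranked form on the moderated t-statistics.

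Samples with the same number were taken as paired where every correlation of their deviations from the group means was above 0.1 or the samples came from the same line, decided before the calls of the fits were compared. This held for cold against warm CBF2Δc plants, with correlations from 0.152 to 0.283, where the numbers follow the lines, and for no other comparison. The main model had no pairing term, so the calls reported for cold against warm CBF2Δc plants are unpaired. Pairing entered only the alternative with the replicate number as a block. The fit and the calling rule were tested on simulated data with 200 changed features, starting from the filtered features. The noise was independent between samples, with 1 spread per feature in all groups and no line differences. The fit recovered from 92.5% to 98.5% of changes of 1.5 log2 units and at least 95.5% of changes of 2 log2 units, over all 11 comparisons, with at most 6 false calls. These values do not cover differences between lines or unequal spread between groups.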

Results

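Cold for 24 h changed 2680 of 14578 features in wild-type plants (1274 up, 1406 down), and overexpression of CBF1, CBF2 and CBF3 without cold changed 369, 362 and 525. The overexpressors raised 180 features in common, of which 137 also rose in the wild type in the cold. CBF2Δc changed 3 features in warm plants and 122 in the cold. The leading component of the 28 arrays held 56.0% of the variance and the next 15.7%. Errors after log2 changes are standard errors of the fit, errors after levels and scores are standard deviations of 4 samples, and p-values measure the spread between these samples only.

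In the wild type, genes for cold-protective proteins were among those with the strongest rises in the cold. COR15A, which encodes a cold-induced protein of the chloroplast stroma, rose from 4.46 ± 0.36 to 12.16 ± 0.19, a log2 change of 7.70 ± 0.25 (adjusted p = 1.14e-17). Its neighbour COR15B rose by 5.84 ± 0.20, the dehydrin gene LTI30 by 5.36 ± 0.40 and LEA4-5, which encodes a late embryogenesis abundant protein, by 5.32. Among named genes AT1G16850 had the largest change, 8.28 ± 0.66 (adjusted p = 1.35e-10), and AT1G48100 (5.68), BETA-VPE (5.42), AT4G36010 (5.29), AT1G80130 (5.21) and AT4G01870 (4.86) were the other named genes among the 10 highest. AT1G16850, AT1G48100, BETA-VPE and LEA4-5 lay under the detection level of 4 in warm plants, as EXPA8, AT4G27450, AT3G06070, AT1G80180 and AT2G34620 did in the cold, so the size of their change depends on the background floor. EXPA8, which encodes an expansin of the growing cell wall, fell by 5.15 ± 0.47, from 8.91 ± 0.30 to 3.76 ± 0.50. AT4G27450 (-4.94), AT1G51400 (-4.59), AT1G23390 (-4.57), AT3G06070 (-4.25), AT5G16030 (-3.96), AT1G80180 (-3.94), AT2G34620 (-3.87), AT1G55960 (-3.84) and AT3G26510 (-3.83) completed the 10 lowest named genes, and some unnamed probe sets rose or fell further.

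Some sugar and starch genes also rose in the wild type in the cold, 4 of 10 sugar transporter genes and 3 of 5 starch genes, while neither list passed its test (adjusted p = 0.483 and 0.208). The sugar transporter genes SWEET13 (4.58), SWEET4 (2.44), SWEET1 (1.86) and TMT2 (2.14) rose, as did APL3 (2.59) and APL4 (2.28), which encode large subunits of ADP-glucose pyrophosphorylase. Cell-wall genes went in both directions, with XTH20 at 2.87, EXLA2 at 2.38, EXPA4 at -1.96 and GH9B13 at -2.52. The zinc-finger gene STZ rose by 3.21, PUB19 by 3.57, UGT73C1 by 3.12 and GSTU25 by 3.38, while GSTU18 fell by 2.38. Of the chaperone genes, Hsp70-2 rose by 2.77 and Fes1A by 2.62, while Fes1B fell by 2.1. CHLM, which encodes a methyltransferase of chlorophyll synthesis, fell by 1.88, and the autophagy genes ATG8E and ATG8F fell by 2.03 and 2.00. TIL, a lipocalin gene, rose by 2.69. SWEET13, SWEET4, APL3, APL4 and UGT73C1 lay under the detection level in warm plants.

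**Figure D1:**
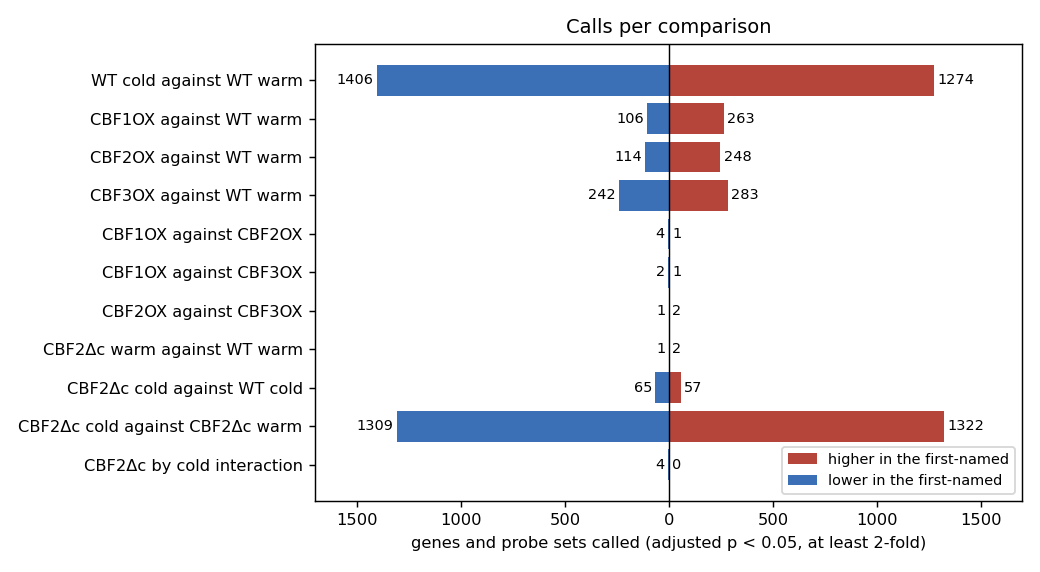
Number of features called higher and lower in each comparison, with 4 samples per group and no error bars. Cold changed 2680 features in the wild type and 2631 in CBF2Δc plants, against 3 for CBF2Δc in warm plants.

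Of the classical CBF target genes, 4 were measured, COR15A, COR15B, LTI30 and COR47 (2.64), and 4 rose in the cold, also 4 when adjusted over the list alone. The list had an adjusted p of 7.06e-06, and an adjusted p = 0.138 with an estimated correlation. Of 6 dehydrin and related genes, 6 rose, DI21 by 2.06 (adjusted p = 6e-07, and adjusted p = 0.138 with an estimated correlation). The clock genes GI (3.44), COR27 (2.93) and AT4G33980 (2.32), 3 of 3 measured and 3 over the list alone, also rose (adjusted p = 0.00186, and adjusted p = 0.203 with an estimated correlation). Of 5 genes of the phenylpropanoid and anthocyanin pathway, 3 rose, UGT78D2 by 1.86, AT4G14090 by 1.57 and DFR by 1.22, also 3 over the list alone, while the list did not pass (adjusted p = 0.0663) and the call of DFR ended without single samples. Of 9 genes on the list called flavonoid modification, which was built from gene symbols, 6 rose. Among them were UGT78D3 (1.86, like AT4G14090 under the detection level in warm plants), HYH (1.55) and UGT78D1 (1.53). The list had an adjusted p of 0.00305, and an adjusted p = 0.405 with an estimated correlation.

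Photosynthesis genes had lower values in the cold. Of 26 nuclear photosynthesis genes, 9 fell and 0 rose, among them LHCB4.2, which encodes an antenna protein (-1.85), and the photosystem II assembly genes LPA2 (-1.85), PSB27 (-1.60) and PAM68 (-1.53). The list had a median of -0.52 (adjusted p = 7.97e-05, and adjusted p = 0.496 with an estimated correlation). Of 67 plastid-encoded genes, 14 fell and 1, rps16 (1.21), rose. The largest falls were those of rps18 (-1.70), psbB (-1.44), ndhH (-1.38) and psbD (-1.27), and the median was -0.64 (adjusted p = 2.7e-07, and adjusted p = 0.627 with an estimated correlation). The shorter photosynthesis list had 1 of 4 genes lower, also 1 over the list alone (adjusted p = 0.105), and of 3 root marker genes 0 were called, with PYK10 at -0.77, EXPA7 at -0.66 and EXPA18 at -0.43 (adjusted p = 0.483).

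Overexpression of each CBF raised the same cold-protective genes in warm plants. COR15A rose by 8.11 ± 0.25 in CBF1OX (adjusted p = 3.17e-18), 8.25 ± 0.25 in CBF2OX (2.05e-18) and 8.10 ± 0.25 in CBF3OX (1.61e-18), to levels of 12.57 ± 0.45, 12.71 ± 0.42 and 12.56 ± 0.25. In the order CBF1OX, CBF2OX, CBF3OX, AT1G16850 rose by 6.81, 7.41 and 7.50, COR15B by 5.81, 6.18 and 6.09, LTI30 by 4.21, 4.99 and 4.78, and COR47, another dehydrin gene, by 1.90, 2.31 and 2.18. AT2G43620 rose by 5.43, 5.90 and 5.21, AT2G24560 by 4.15, 5.0 and 5.49, AT1G48100 by 3.62, 4.24 and 4.22, and AT1G68500 by 3.64, 4.05 and 3.72. The defensin gene PDF1.2b fell in each, by 2.12, 2.08 and 2.1 (adjusted p = 2.46e-05, 1.62e-05 and 1.86e-05). AT3G16530 changed by -1.54, -2.62 and -2.51, AT1G23130 by -2.07, -2.07 and -2.42, AT3G29410 by -1.93, -1.81 and -2.05, and SWEET16 by -1.26, -1.21 and -1.46. AT1G16850, AT2G24560 and AT1G48100 in warm wild-type plants and SWEET16 in the overexpressors lay under the detection level.

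The classical CBF targets and the overlapping list of dehydrin and related genes kept their calls with an estimated correlation in every overexpressor. In CBF1OX, CBF2OX and CBF3OX 4 of 4 rose, 4 over the list alone, with an adjusted p of 8.52e-21, 6.76e-23 and 1.2e-19, and adjusted p = 0.000605, 0.000571 and 0.000638 with an estimated correlation. Of 6 dehydrin and related genes 5, 4 and 5 rose, and 6, 4 and 5 over the list alone (adjusted p = 0.0014, 0.00144 and 0.00244 with an estimated correlation). Of 10 sugar transporter genes, 1, 2 and 2 rose and 1, 1 and 2 fell (adjusted p of the list 0.853, 0.836 and 0.67), with SWEET1 up by 1.65, 1.82 and 1.63 in each overexpressor and SWEET16 down in each. Of 20 expansin and XTH genes, 3, 2 and 3 rose and 0, 0 and 2 fell (adjusted p of the list 0.921, 0.533 and 0.983), with XTH32 up by 1.23, 1.12 and 1.52. SWEET13 rose in CBF3OX (1.94), SWEET10 in CBF2OX (2.03), and APL4 (1.18), PUB19 (1.17) and XTH20 (1.65) in CBF1OX. EXLA2 rose in CBF1OX and CBF3OX, calls that ended without single samples. These examples are not complete, and a gene given for 1 overexpressor is not thereby particular to it. The plastid-encoded genes had medians of -0.24, -0.22 and -0.20 with 0 called (adjusted p = 5.08e-06, 0.000133 and 0.00131, and adjusted p = 0.633, 0.665 and 0.73 with an estimated correlation). Of the root markers, EXPA18 fell by 1.0 in CBF3OX to a level under the detection level, 1 of 3 measured and 1 over the list alone (adjusted p of the list 0.0644), a call lost after centring arrays on their medians and without single samples, and the 5 root hair and root genes had a median of -0.53 in CBF2OX (adjusted p = 0.0498, and adjusted p = 0.627 with an estimated correlation). The tubulin genes in CBF2OX (adjusted p = 0.0296, and adjusted p = 0.405 with an estimated correlation), the starch genes in CBF3OX (adjusted p = 0.0268, and adjusted p = 0.227 with an estimated correlation) and the ATG8 genes in CBF3OX (adjusted p = 0.0393, and adjusted p = 0.633 with an estimated correlation) passed at the preset correlation alone. The count for CBF1OX was 70 with line G5 alone, 1166 with line G39 alone, 35 when only the compared groups were fitted, and 556, 629, 150 and 140 without replicates 1, 2, 3 and 4. For CBF2OX line E2 alone gave 752, line means as samples gave 163, 226 and 317 for the 3 overexpressors, and the calls of APL4, PUB19, XTH20, AT1G23130, AT3G29410 and SWEET16 in CBF1OX ended without replicate 3 or 4, and those of AT1G23130 and XTH32 in CBF2OX and SWEET13 in CBF3OX without single samples. With line G5 alone the calls of SWEET1 (0.84), SWEET16 and XTH32 in CBF1OX ended, as they did with only the compared groups fitted, and with line E24 alone those of SWEET16 and XTH32 in CBF2OX. The calls of COR47, AT2G24560, AT1G48100 and AT1G68500 in CBF1OX also ended with only the compared groups fitted. AT2G24560 differed by -4.42 between the lines of CBF1OX (G5 minus G39). The call of AT3G29410 also ended in CBF2OX in 7 leave-outs of single samples and in CBF3OX without replicate 2. PYK10 stood at 12.30 in line G5 and 11.38 in line G39.

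**Figure D2:**
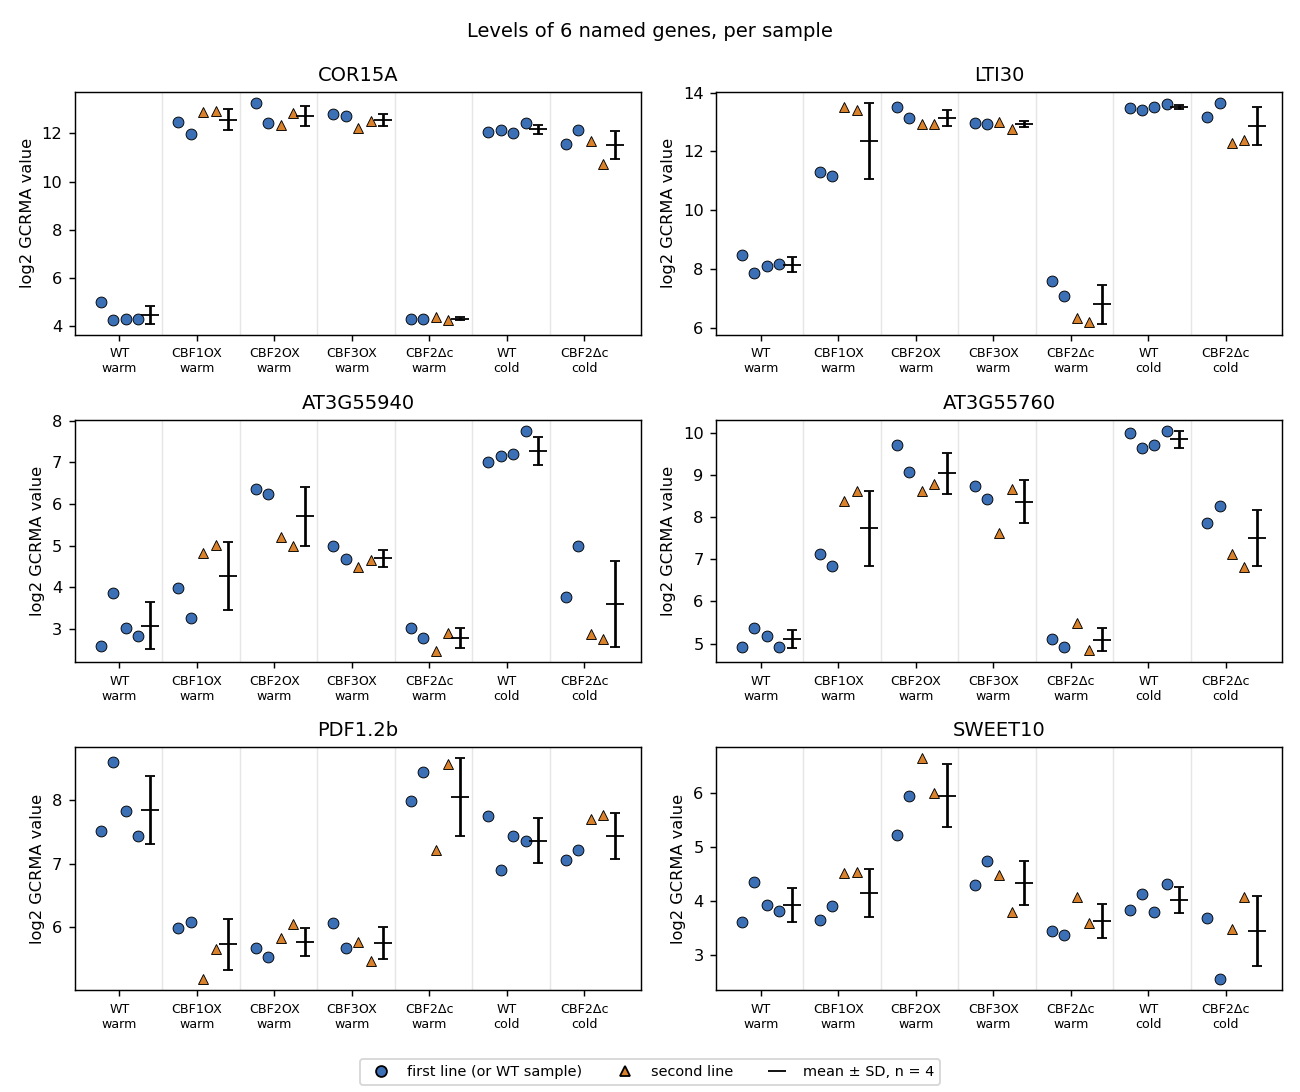
Log2 level of COR15A, LTI30, AT3G55940, AT3G55760, PDF1.2b and SWEET10 in each sample of the 7 groups, with mean ± SD of 4 samples and triangles for the second line of each construct. COR15A stood near 12.57 in CBF1OX and 12.16 in cold wild-type plants against 4.46 in warm ones, and AT3G55940 stood at 3.60 in cold CBF2Δc plants against 7.28 in cold wild-type plants.

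COR15A, COR15B, LTI30, COR47 and AT1G16850 were among 180 features raised in all 3 overexpressors, and PDF1.2b and SWEET16 among 48 lowered ones, of which 81 and 18 were named genes. From the sizes of the separate lists alone, 0.0869 and 0.0138 would be shared. The CBF1OX and CBF2OX changes correlated at 0.858, those of CBF1OX and CBF3OX at 0.884 and those of CBF2OX and CBF3OX at 0.883, with a covariance of 0.163, 0.180 and 0.188. Because these comparisons share the warm wild-type samples, unchanged groups simulated against the same controls gave a correlation of 0.50, a covariance of 0.0197 at most and 0 shared calls. With 2 separate controls for each of a pair the correlations were 0.761 to 0.811. Without CBF1OX replicate 3 or 4, both of line G39, the raised and lowered features common to all 3 came to 134 and 126, against 228 with every sample, and those shared with the cold to 110 and 104, against 168.

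In the wild type in the cold, COR15A, COR15B, LTI30, COR47 and AT1G16850 rose as they did in the overexpressors, and 137 of the 180 raised features (76.1%) rose where 15.7 would do so by list sizes. Of the 48 lowered features 31 (64.6%) fell in the cold, where 4.63 would do so. With 2 warm controls for the overexpressors and the other 2 for the cold, 80 of 98 raised (81.6%) and 79 of 93 (85.0%), and 11 of 14 and 7 of 10 lowered features, were shared with the cold, where 8.48, 8.21, 1.28 and 1.02 would be. Changes of the 3 overexpressors correlated with the cold changes at 0.489, 0.442 and 0.488, against 0.39 to 0.471 with split controls and 0.50 in simulated unchanged groups, with a covariance of 0.188, 0.178 and 0.212 against a simulated covariance near 0.0197. Picked after its values were seen, AT3G44970 rose by 2.49, 2.53 and 2.72 in the overexpressors and stood at -0.04 in the cold, and XTH32 stood at 0.40. PDF1.2b (-0.48), AT1G23130 (-0.50), AT1G67860 (-0.65) and SWEET16 (-0.94) were not called in the cold. AT5G59080 and AT2G38870, also picked after their values were seen, rose in all 3 overexpressors and fell in the cold, by 2.06 and 1.89. Of all features raised in the cold, 10.8% rose in all 3 overexpressors and 17.0% in at least 1, and of those lowered in the cold 2.2% and 12.0% fell.

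Between overexpressors, few features differed. SWEET10, a sugar transporter gene, was the single named gene, with 5.96 ± 0.58 in CBF2OX against 4.15 ± 0.45 in CBF1OX (-1.81 ± 0.29 for CBF1OX minus CBF2OX, adjusted p = 0.00594) and 4.33 ± 0.40 in CBF3OX (1.62 ± 0.29, adjusted p = 0.0408). The other calls were 5 unnamed probe sets. Among warm plants 254074_at was high in CBF1OX alone, 254066_at in CBF3OX alone, and 254075_at in CBF2OX and CBF2Δc plants alone. These may measure the introduced genes and need not be differences in the response to them. 254074_at stood at 8.62 ± 1.51 in CBF1OX and differed by 6.32 (adjusted p = 2.54e-11) from CBF2OX and 6.34 (2.36e-11) from CBF3OX. 254075_at stood at 11.80 ± 0.29 in CBF2OX (-8.31 and 8.41, adjusted p = 1.34e-17 and 5.06e-18), and 254066_at at 12.09 ± 0.20 in CBF3OX (-8.35 against CBF1OX, adjusted p = 8.4e-21, and -8.39 against CBF2OX). 263981_at (-1.97 and -1.72) and 248910_at (-1.14) were the others in the comparisons of CBF1OX with CBF2OX and CBF3OX. The lower groups lay under the detection level of 4 for 254074_at (2.30 in CBF2OX and 2.28 in CBF3OX), 254075_at, 254066_at and 263981_at (2.47 in CBF1OX), so the sizes of these differences depend on the background floor. Over the 180 commonly raised features, whose choice by a rise in all 3 overexpressors favours small differences and leaves out genes raised by 1 alone, the median difference was -0.18 for CBF1OX minus CBF2OX, -0.11 for CBF1OX minus CBF3OX and 0.05 for CBF2OX minus CBF3OX, and 60%, 64.4% and 65% had a 95% interval inside 2-fold. The mean score over these features was 1.99 ± 0.96, 2.16 ± 0.30 and 2.13 ± 0.11 (exact p = 0.743, 0.686 and 0.914 for the 3 pairs, n = 4 each, smallest possible 0.0286). The root hair and root genes had a median of 0.41 for CBF1OX minus CBF2OX (adjusted p = 0.0186, and adjusted p = 0.557 with an estimated correlation) and 0.50 for CBF1OX minus CBF3OX (adjusted p = 0.0155, and adjusted p = 0.557 with an estimated correlation). With lines G5, E2 and A28 alone, 439, 340 and 4 features differed, and with lines G39, E24 and A30 alone 448, 134 and 135, against 5, 3 and 3 with all samples. SWEET10 lost its call against CBF1OX without CBF1OX replicate 1 or CBF2OX replicate 3, when 3 features were called, and its call against CBF3OX in 13 alternatives, among them 6 leave-outs of single samples, centring arrays on their medians and the line as a random block.

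In warm plants CBF2Δc changed 3 features. The unnamed probe set 254075_at, high in CBF2OX, rose from 3.41 ± 0.25 to 13.30 ± 0.32 (9.89 ± 0.27, adjusted p = 1.77e-19), a size that depends on the background floor. It may measure the introduced gene and need not be a response to it. AT1G49740 rose by 1.09 ± 0.14 (adjusted p = 0.000197), from 5.74 ± 0.19 to 6.84 ± 0.23, a call that ended with line DN89 alone, without replicate 3 of the warm CBF2Δc plants and with only the compared groups fitted. The unnamed probe set 246481_s_at fell by 3.86 ± 0.48 (adjusted p = 0.000134), from 8.94 ± 0.07 to 5.08 ± 1.58. This call also ended with only the compared groups fitted, when 1 feature, a higher one, was called. In the main fit 246481_s_at was the 1 feature called lower among the 180 raised in all 3 overexpressors, where it stood at 13.66, 13.84 and 13.815. COR15A and the other common overexpressor genes had a median change of 0.11 over 180 features (camera p = 0.136), and their score was 0.096 ± 0.024 against 0 ± 0.043 in the wild type (exact p = 0.0286, the smallest possible, and 0.238 adjusted over 25 tests, n = 4). The root markers, among them PYK10, had a median of -0.57 (adjusted p = 0.0168, and adjusted p = 0.405 with an estimated correlation) and the longer root hair and root list of -0.55 (adjusted p = 0.0135, and adjusted p = 0.557 with an estimated correlation), with 0 called. The plastid-encoded genes had a median of -0.18 (adjusted p = 5.78e-08, and adjusted p = 0.624 with an estimated correlation). Line DN96 alone gave 139 calls.

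**Figure D3:**
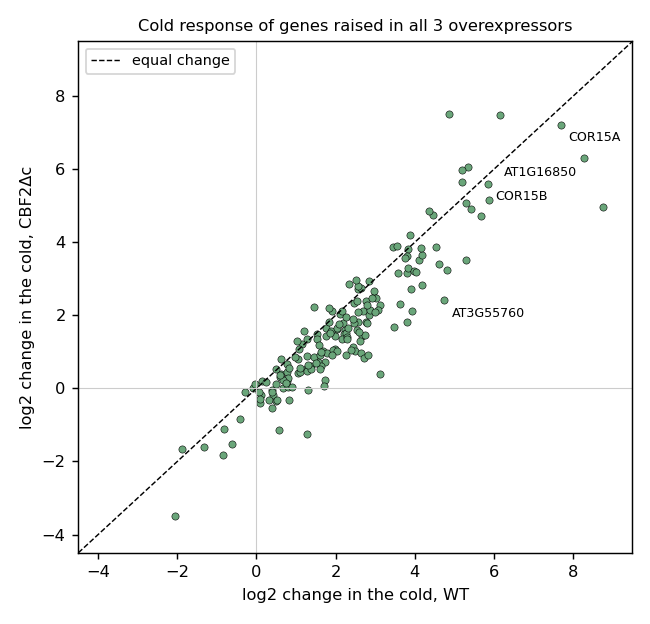
Log2 change in the cold in wild-type plants (horizontal axis) and CBF2Δc plants (vertical axis) of the 180 features raised in all 3 overexpressors, each a difference of means of 4 samples without error bars, with a dashed line of equal change. AT3G55760, which changed by 4.75 in the wild type and 2.41 in CBF2Δc plants, lay under the line, and the features were chosen with the warm wild-type samples that the horizontal axis also uses.

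In the cold, CBF2Δc plants had lower levels of a set of cold-induced genes. AT3G55940 stood at 3.60 ± 1.04 against 7.28 ± 0.33 in the wild type (-3.68 ± 0.41, adjusted p = 1.03e-05), the lower of these under the detection level of 4, AT3G55760 at 7.51 ± 0.66 against 9.85 ± 0.20 (-2.34, adjusted p = 0.000234) and AT3G09540 at 5.55 ± 1.12 against 8.03 ± 0.20 (-2.48, adjusted p = 0.00117). AT2G27830 (-1.80), AT5G55050 (-1.72), AT5G42570 (-1.70), AT1G64890 (-1.69), AT4G26010 (-1.64), XTH20 (-1.61) and AT3G53990 (-1.57) were also lower. AT5G54300 (2.11, adjusted p = 0.00186), AT5G58570 (1.96), AT5G53710 (1.96), AT4G22470 (1.86) and MSRB6, which encodes a methionine sulfoxide reductase (1.84), were higher, as were AT1G09500 (1.52), AT4G38810 (1.30), AT2G21300 (1.26), AT5G45950 (1.22), APL3 (1.2), UGT73C1 (1.2) and TBL37 (1.08), with AT5G54300, AT1G09500 and AT2G21300 under the detection level in cold wild-type plants. The calls of AT4G26010, XTH20, AT1G09500, AT5G45950, APL3, UGT73C1 and TBL37 ended without at least 1 single sample, and those of AT2G27830, AT4G26010, XTH20, AT3G53990, APL3 and UGT73C1 with line DN89 alone. Calls of lower genes that ended with only the compared groups fitted included AT3G09540, AT2G27830, AT5G55050, AT5G42570, AT1G64890, AT4G26010 and AT3G53990. Those of higher genes included AT5G54300, AT5G53710, AT4G22470, MSRB6, AT2G21300, AT5G45950 and APL3. COR15A (-0.63, adjusted p = 0.136), LTI30 (-0.63), COR47 (-0.44) and COR15B (0.06) were not called.

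Of the 65 features lower in cold CBF2Δc plants, among them AT3G55940 and AT3G55760, 39 were raised in the wild type in the cold (5.68 by list sizes), 35 in at least 1 overexpressor (1.61) and 24 in all 3 (0.803), and 6 were lowered in the cold. The overlap with the cold response is raised by the cold wild-type samples that both comparisons share. Of the 57 higher features, 19 were raised and 13 lowered in the wild type in the cold. The share of higher features was 46.7%, and 35.3% or 36.7% after centring arrays on their medians or quantile normalization. The root hair and root genes had a median of -0.49 with 0 called (adjusted p = 0.0192, and adjusted p = 0.557 with an estimated correlation), the expansin and XTH genes -0.32 (adjusted p = 0.0428, and adjusted p = 0.172 with an estimated correlation) and the chaperone genes 0.27 (adjusted p = 0.011, and adjusted p = 0.325 with an estimated correlation). Line DN96 alone gave 376 calls, line DN89 alone 91, line means 64, fitting only the compared groups 26 and leaving out replicate 3 of the cold CBF2Δc plants 75.

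The cold response of CBF2Δc plants shared most of its members with that of the wild type. COR15A rose by 7.22, LTI30 by 6.07, COR15B by 5.60, LEA4-5 by 5.50, APL3 by 3.88, SWEET13 by 4.71 and PUB19 by 4.59, and EXPA8 fell by 5.20. The clock genes GI (4.11), COR27 (3.52) and AT4G33980 (3.04) rose (adjusted p = 0.000584, and adjusted p = 0.172 with an estimated correlation), and PYK10 and NAI2, which encode proteins of endoplasmic reticulum bodies, fell by 1.03 and 1.52. The call of PYK10 ended after centring arrays on their medians, with line DN96 alone and without single samples. The classical CBF targets rose, 4 of 4 and 4 over the list alone (adjusted p = 7.06e-06, and adjusted p = 0.138 with an estimated correlation), and of the nuclear photosynthesis genes 6 fell (adjusted p = 0.000456, and adjusted p = 0.557 with an estimated correlation). Of 2631 calls, 1322 up and 1309 down, 1021 were up and 1033 down in both genotypes and 1 was opposite. The cold changes of the genotypes correlated at 0.936 with a slope of 0.925 and share no sample.

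The test of the difference between cold responses called 4 features, all with a negative difference for CBF2Δc plants. AT3G55940 differed by -3.39 ± 0.58 (adjusted p = 0.0178), with 3.08 in warm wild-type plants, 2.79 in warm and 3.60 in cold CBF2Δc plants all under the detection level of 4, so the size of this difference depends on the background floor. AT2G27830 differed by -2.53 ± 0.46 (adjusted p = 0.0367), going from 6.60 to 5.34 in CBF2Δc plants and from 5.87 to 7.14 in the wild type. AT1G53400 differed by -1.61 ± 0.21 (adjusted p = 0.000457), going from 7.58 to 6.29 and from 7.52 to 7.85. The unnamed probe set 254075_at, differed by -3.80 ± 0.38 (adjusted p = 3.43e-06), with 3.41 in warm wild-type plants under the detection level and 13.30 and 13.55 in warm and cold CBF2Δc plants near the highest value of the table (14.53), so a weaker response cannot be read from it. The chaperone genes had a median of 0.46 (adjusted p = 0.00244, and adjusted p = 0.196 with an estimated correlation), the clock genes 0.67 (adjusted p = 0.0389, and adjusted p = 0.496 with an estimated correlation) and the plastid-encoded genes 0.17 (adjusted p = 0.00565, and adjusted p = 0.775 with an estimated correlation). The count was 0 with line means, 7 and 65 with line DN89 or DN96 alone, 20 with array weights, 2 without CBF2Δc warm replicate 4 or warm wild-type replicate 4, 18 and 7 without cold CBF2Δc replicate 2 or 4, and 8 and 15 without cold wild-type replicate 3 or 4. The calls of AT3G55940, AT2G27830 and AT1G53400 ended with line DN89 alone, that of AT3G55940 also without CBF2Δc warm replicate 4 and without warm wild-type replicate 1 or 4, and that of AT2G27830 in 9 of the leave-outs.

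Of the genes raised in all 3 overexpressors, most had lower values in cold CBF2Δc plants than in cold wild-type plants. AT3G55760, AT3G09540, AT2G27830 and AT5G42570 were among 24 of these 180 features called lower, while 0 were called higher and 142 had a lower value. The median difference was -0.41, with a camera p of 1.11e-16, and p = 0.193 with an estimated correlation. The mean score was 1.75 ± 0.34 against 2.24 ± 0.10 in the wild type, a difference of -0.48 (exact p = 0.0571, and 0.286 adjusted over 25 tests, n = 4, smallest possible 0.0286). The permutation of the median gave an exact p = 0.0857. Genes lowered in all 3 overexpressors had a score of -1.53 ± 0.08 in cold CBF2Δc plants and -1.51 ± 0.09 in cold wild-type plants (exact p = 0.657, n = 4), with 0 of 48 called between them by limma. Genes raised in the cold in no overexpressor, chosen on the same cold wild-type samples, had a score of 1.64 ± 0.15 in CBF2Δc plants and 1.58 ± 0.05 in the wild type (exact p = 0.486, n = 4), and genes lowered in the cold in no overexpressor -1.44 ± 0.06 and -1.58 ± 0.09 (exact p = 0.0571, n = 4). The median was -0.18 with line DN89 alone and -0.73 with line DN96 alone.

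**Figure D4:**
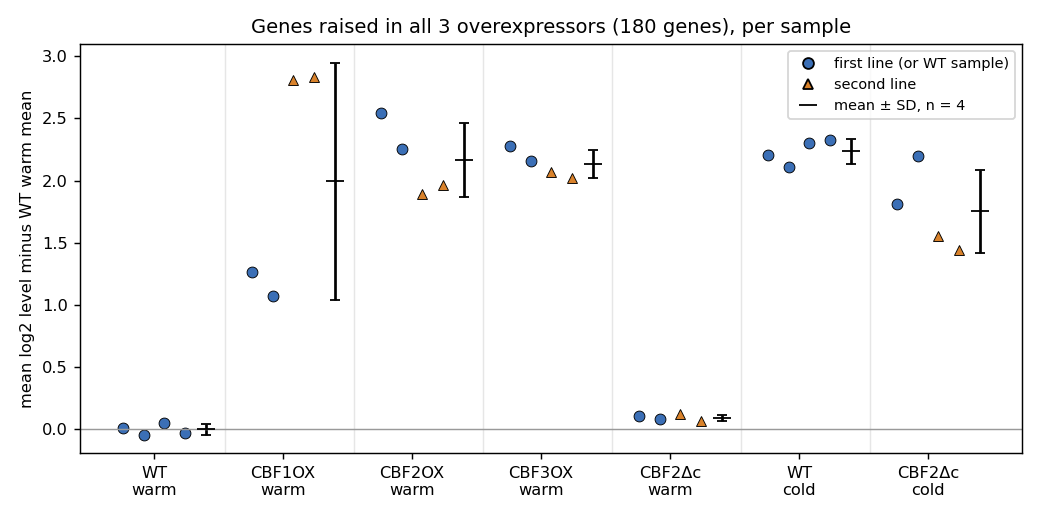
Mean log2 level over the 180 features raised in all 3 overexpressors, relative to warm wild-type plants, per sample of the 7 groups with mean ± SD of 4 samples and triangles for the second line of each construct. The CBF1OX samples spread most (1.99 ± 0.96), and cold CBF2Δc plants stood at 1.75 ± 0.34 against 2.24 ± 0.10.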

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

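The counts of splits and the test of a mixture in line G5 were chosen before their results were seen, and the other tests of explanations were chosen only after the patterns were seen, as was the comparison of the lines.

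Line G39 of CBF1OX had a larger response than line G5, with a score over the commonly raised features of 2.82 against 1.17, and 856 features differed between the lines, AT2G24560 by -4.42 and AT1G16850 by -3.62 (G5 minus G39). Root genes moved with the lines too, PYK10 from 12.30 in G5 to 11.38 in G39 and NAI2 from 8.09 to 6.99, with a list median of 0.74 (adjusted p = 0.0134, and adjusted p = 0.254 with an estimated correlation), and root tissue as a source was not tested for this pattern. The CBF3OX arrays spanned 1.31 to 1.61 in the actin 3′ to 5′ difference, with all but replicate 1 at 1.55 or above, and differed in score by 0.2575 at most. Within that span this argues against an RNA quality difference. G39 stood at 1.46, but G5 at 1.70 lay above every CBF3OX array, so the comparison cannot decide the question for G5. A candidate explanation is the level of the construct, since the unnamed probe set 254074_at stood 2.55 log2 units higher in G39 than in G5, with both G39 samples above both G5 samples, though which gene it measures is not given in the sources used here. A mixture of responding and non-responding plants in G5 stays open, because genes scattered around a single mixing weight 2.038 times as much as the G5 samples differed, where 2 was the bound set before, with an interval of 1.71 to 2.446 over resampled genes, and the use of the interval was decided after the ratio was seen.

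Genes raised in all 3 overexpressors scored lower in cold CBF2Δc plants than in cold wild-type plants, by -0.48, which did not pass its test. Their score minus that of cold-raised genes of no overexpressor differed by -0.5475 (exact p = 0.0286, unadjusted, the smallest possible with 4 against 4). This largely restates the difference of -0.48, and the permutation takes samples of the same line as independent. Interference of the truncated factor with genes raised by CBF factors is a candidate explanation, which this p cannot establish. The 48 commonly lowered genes showed no sign of it (-1.53 against -1.51, exact p = 0.657, 24 of 48 lower), so the explanation is not extended to them. Against an effect of line DN96 alone, the DN89 mean of 2.006 met the bound written after the values were seen by lying under the lowest wild-type sample (2.108), -0.2304 from the wild-type mean, and by the difference of scores both DN89 samples (0.178 and 0.404) lay under the lowest of 4 wild-type samples (0.504), but it cannot be told apart because 1 of only 2 DN89 samples (1.815 and 2.198) had a score inside the wild-type range. Root genes moved with the lines too, PYK10 standing at 10.48 in DN96, which had the lowest score (1.499), against 11.1 in DN89 and 11.04 in the wild type, and root tissue as a source was not tested for this pattern. RNA quality cannot be told apart, since the 2 DN89 samples differed in the actin 3′ to 5′ difference (1.2 and 1.84) and by 0.3832 in score.

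In CBF2Δc, 132 features differed between the lines in the warm and 159 in the cold, of which 128 and 150 were higher in DN89, among them the peroxidase gene AT5G15180. Less root tissue in the DN96 samples is a candidate explanation, though the aerial part was sampled. PYK10, the root marker of highest level, differed by -0.99 in the warm (12.31 in DN89, 11.32 in DN96). Both DN96 samples lay under both DN89 samples in the warm and in the cold (11.1 and 10.48). In warm wild-type plants PYK10 stood at 11.8 and NAI2 at 7.3, but EXPA7 (4.31), EXPA18 (4.50) and GH9C1 (4.65) lay near the detection level. Whether PYK10 reports root tissue in these aerial samples was not tested. The median root marker differed by -0.96 in the warm, where the root hair and root list passed between the lines (adjusted p = 1.4e-06, and adjusted p = 0.0271 with an estimated correlation). The warm median of DN96 (3.76) lay under the detection level of 4, so the size of that difference depends on the background floor. In the cold both medians (3.79 and 3.44) lay under it and decide nothing. Root tissue cannot be told apart from a regulatory difference between the lines, since each line is its own set of samples, and no biological explanation apart from tissue was tested. The actin 3′ to 5′ difference overlapped between the lines in the warm, with a mean of -0.215 (DN96 minus DN89), and in the cold, against RNA quality as the cause.

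In CBF2OX 332 features differed between lines E2 and E24, and in CBF3OX 1, AT5G55070, between A28 and A30. The tests between overexpressors called 5, 3 and 3 features, and the test of a different cold response in CBF2Δc plants called 4.

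A sample far from the other 3 of its group was found in 6 of 112 groups of values, where chance gives about 1 in 20, here 5.6. These were replicate 1 of cold CBF2Δc for the score of commonly lowered genes, with a gap of 0.913 of the group's range, replicate 2 of CBF3OX and replicate 1 of warm CBF2Δc for 254074_at (both 1, at the floor), replicate 1 of CBF1OX for 254075_at (0.98) and for 263981_at (0.909), and replicate 1 of CBF2OX for 263981_at (0.979).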

How the results depend on the processing

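The use of cold wild-type replicates 3 and 4 to choose genes, the scores per sample and the model with a mean per line were added only after the results were seen, and the other alternatives here were planned.

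Of the 255 pairs of gene and comparison that the naming rule gave, 0 took the opposite sign under an alternative, 175 stayed on their side of the threshold under every alternative run, and 92.3% of all alternative values did. Genes picked after their values were seen and differences between lines were not recomputed. Counts of the cold responses of the wild type and of CBF2Δc plants moved by more than 1.5 times only without a minimum change.

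Many counts moved with the choice of lines. With line means as samples, which leaves fewer samples, the counts against warm wild type were 163, 226 and 317 for CBF1OX, CBF2OX and CBF3OX, 3 for CBF1OX against CBF2OX, 64 for CBF2Δc against wild type in the cold and 0 for the difference in cold response, and 123 features changed in all 3 overexpressors, 101 of them also in the cold. With the lines G5, E2, A28 and DN89 alone, CBF1OX gave 70, CBF2OX 752, CBF1OX against CBF2OX 439, CBF1OX against CBF3OX 340 and the difference in cold response 7, with 67 features in all 3 and 58 of them in the cold. With the lines G39, E24, A30 and DN96 alone, CBF1OX gave 1166, the differences between overexpressors 448, 134 and 135, CBF2Δc 139 in the warm and 376 in the cold, and the difference in cold response 65. The line as a random block, with a correlation of 0.226 within lines, gave 13 for the difference in cold response. The cause was not tested beyond the comparison of the lines.

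Fitting only the compared groups gave 35 for CBF1OX and 1 each for CBF1OX against CBF2OX and against CBF3OX. For CBF2Δc it gave 1 in the warm and 26 in the cold. This fit leaves fewer samples to estimate the spread, but it gave 2682 for the wild type in the cold, 377 for CBF2OX and 580 for CBF3OX. Fewer samples alone therefore do not account for the drops. Array weights gave 6 for CBF2Δc in the warm and 20 for the difference in cold response, for which centring arrays on their medians gave 9 and quantile normalization 13. The cause was not tested. A filter at log2 6, which tests fewer genes, gave 3 for CBF1OX against CBF2OX.

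Without a minimum change the calls rose by construction, to 7627 in the wild type in the cold, 840, 737 and 1278 in the overexpressors, 791 for CBF2Δc in the cold, 7637 for its cold response, 407 in all 3 overexpressors and 307 of these in the cold. An adjusted p of 0.01 gave by construction fewer, 197 for CBF1OX, 349 for CBF3OX, 69 for CBF2Δc in the cold, 2 for the difference in cold response, 138 in all 3 overexpressors and 111 of these in the cold. With the warm controls split, which leaves 2 for each side, 91 and 86 were shared with the cold. With an estimated correlation 6 of 45 list calls were left.

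Leaving out single samples gave 2631 to 2760 calls in the wild type in the cold, 140 to 629 for CBF1OX, 271 to 463 for CBF2OX, 430 to 508 for CBF3OX, 3 to 7 for CBF1OX against CBF2OX, 3 in each case against CBF3OX, and 2 to 4 for CBF2OX against CBF3OX. For CBF2Δc it gave 2 to 4 in the warm, 75 to 163 in the cold, 2570 to 2706 for its cold response and 2 to 18 for the difference in cold response. In all 3 overexpressors 126 to 286 changed, 104 to 206 of them in the cold, and the median of the commonly raised features in cold CBF2Δc plants ran from -0.58 to -0.33.

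With the replicate number as a block, the cold response of CBF2Δc plants, the comparison whose numbers follow the lines, had 2632 calls, the difference in cold response 3, and the features common to the overexpressors 218. No count of calls moved by more than 1.5 times, and the median was -0.41.

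Signal over background limits changes of dim transcripts. On each array between 10.6% and 12.6% of values lay at the lowest value, and between 60.7% and 61.5% of probe sets were above the detection level.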

Other observations

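The comparison of the lines, the scores and the measuring of cold genes with cold wild-type replicates 3 and 4 as choosers were chosen only after the results were seen, and the splits of samples were planned.

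The lines of CBF1OX differed in the size of the response, those of CBF2OX less, and those of CBF3OX hardly. Against warm wild-type plants, 76 features were called in line G5 and 1172 in G39, 753 in E2 and 344 in E24, and 660 in A28 and 549 in A30, with correlations between the responses of a construct's lines of 0.575, 0.672 and 0.894. Genes higher in G39 than in G5, picked after their values were seen, were AT4G36700 (-5.67 for G5 minus G39), AT1G03990 (-3.96) and the sugar transporter gene SWEET13 (-2.62), which was also higher in E2 than in E24, by 2.60. Genes higher in G5 were AT3G16670 (4.92), AT2G16005 (3.79) and AT1G67860 (3.11). The classical CBF targets had a median of -1.11 for G5 minus G39 (adjusted p = 0.0288 with an estimated correlation). Of the features that differed between lines in both CBF1OX and CBF2OX, 123 had the same direction in G39 minus G5 as in E2 minus E24, higher or lower in both, and 8 the opposite.

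Of the 3 unnamed probe sets that set the overexpressors apart, 254066_at and 254075_at were also higher in the cold. In the wild type 254066_at stood at 3.71 in the warm and 8.12 in the cold, and at 9.12 in cold CBF2Δc plants, and 254075_at stood at 3.41 in the warm and 7.47 in the cold, while 254074_at stood at 2.25 and 2.38. By line 254074_at stood at 7.35 in G5 and 9.90 in G39, 254075_at at 11.92 in E2 and 11.68 in E24, and 254066_at at 12.26 in A28 and 11.92 in A30. Which genes they measure is not given in the sources used here.

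When the samples of each comparison were divided otherwise into groups of the same sizes, for most counts no other split gave as many calls. A chance division of independent samples is thus an unlikely source of these counts. For the overexpressors and CBF2Δc, however, the splits took samples of the same line as independent, so chance differences between lines are not excluded. The wild-type cold response was the 1 split of 35 with so many calls (2680 against 4 at most otherwise), as were CBF1OX (369 against 24), CBF2OX (362 against 5), CBF3OX (525 against 0), CBF2Δc in the warm (3 against 0) and in the cold (122 against 22), and the cold response of CBF2Δc plants (2631 against 132 at most in any other split, whether or not it parted as many pairs of a line). For the features in all 3 overexpressors (228 against 1) and those also changed in the cold (168 against 0), 1 of 100 splits, the real one, gave as many.

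For the number of calls between overexpressors and for the difference in cold response, the splits could not exclude chance. Of 35 splits, 6 gave as many calls for CBF1OX against CBF2OX (5 against 360), 4 for CBF1OX against CBF3OX (3 against 137) and 3 for CBF2OX against CBF3OX (3 against 21), and 5 of 100 did for the difference in cold response (4 against 50). The split with 360 calls put the G5 samples with the E24 samples, and that with 137 calls parted G5 from G39, so they point to a structure of the samples by line and are no clean reference for chance. The counts say nothing against single calls: 254074_at, 254075_at and 254066_at did not overlap between the overexpressor in which each was high and the others.

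Cold genes of the wild type as a whole had a median difference between CBF2Δc and wild-type plants in the cold of 0.03 for raised and 0.14 for lowered ones, and with genes chosen and measured in separate wild-type samples of 0.07 and 0.08 for raised and 0.18 and 0.05 for lowered ones. Of 64 control probe sets, limma called 0 in any of the 11 comparisons, with 1 to 17 at an unadjusted p under 0.05.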
